A study of Mus musculus with 4 samples.

How the data were processed

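LSK cells of WT, Aspp1-/-, p53-/- and Aspp1-/-p53-/- mice were profiled on 4 Agilent mouse gene expression arrays of design 028005, with 1 colour (Cy3) and 1 array per genotype. Per the labels' protocols, RNA was purified with the RNeasy Micro Kit and amplified and labelled with the Low Input Quick Amp kit, and RNA of 3 mice was pooled per genotype. Groups were taken from the labels' genotype or, for the arrays without p53, from the sample titles. All arrays lay on 1 slide and were scanned in 1 session, with WT and Aspp1-/- in slide row 1 (columns 1 and 2) and p53-/- and Aspp1-/-p53-/- in row 2 (columns 1 and 4). The arrays of row 2 are also those of mice with Mx1-Cre.

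Spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, which also give the mm9 build for probe positions. The deposited processed intensity is background-subtracted and detrended on a linear scale, with a surrogate value for spots not above background, and is not normalised between arrays. The deposited files also hold raw mean and local background intensity and, as other values, flags of 0 or 1 for spots well above background, saturated or non-uniform. The authors' value table holds log2 values, which matched the log2 processed intensity less a constant per array, with each probe centred on its median over the 4 arrays. Differences between arrays in that table had r = 1 with those of the scanner files across 26465 probes. Its 55821 rows included 55675 that matched a probe used here, and its column medians were −0.0661 for WT, −0.0422 for Aspp1-/-, 0.0267 for p53-/- and 0.0478 for Aspp1-/-p53-/-. How the authors chose the constant is not given in the sources used here, and the scale, centring and direction were read from the values.

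Control spots (3671 per array) and spots with an outlier flag (120 for WT, 121 for Aspp1-/-, 171 for p53-/- and 172 for Aspp1-/-p53-/-) were left out. Spots of a probe were averaged, which gave 55675 probes with a value on every array out of 55681. The log2 processed intensity of each array was set relative to its 75th percentile, which was a signal of 570 for WT, 597 for Aspp1-/-, 580 for p53-/- and 535 for Aspp1-/-p53-/-. Between spots of the same probe the median standard deviation on the log2 scale was 0.0536 for WT, 0.0536 for Aspp1-/-, 0.0533 for p53-/- and 0.0540 for Aspp1-/-p53-/-, which is technical and says nothing of mice. Probe names in the files can be old, so 26762 probes were named through their RefSeq accession, 2878 of them with a symbol that differed from the file's, and 3819 only through the symbol in the file. The other 25100 had no RefSeq gene and entered the counts as transcripts.

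A gene was represented by its probe with the highest mean among those well above background on at least 1 array. This left 22935 genes or transcripts, of which 15116 were RefSeq genes and 19117 were well above background on all 4 arrays. With 1 array per genotype a comparison of 2 arrays leaves no residual degree of freedom, and a rule of size was used: a log2 difference of at least 1, or 2-fold. Where a probe was not well above background on the dimmer array the difference is a bound, taken between the brighter value and the higher of the dim probe's own value and the lowest signal among probes well above background on that array, and it is given as "or more" or "or less". Where the dim probe's own value was the higher, the bound is the measured difference and not a strict limit. The lowest signal differed between arrays, so bounds against different arrays cannot be compared in size. Rbfox3, well above background only on the Aspp1-/-p53-/- array, was at 4.82 or more against WT, 4.37 or more against p53-/- and 5.68 or more against Aspp1-/-. Most genes past the rule were bounds. A further probe of the same gene had the same sign for 29 of 43 bounds (67.4%) and 98 of 125 differences measured on both arrays (78.4%) in Aspp1-/-p53-/- against WT, and for 6 of 14 (42.9%) and 14 of 23 (60.9%) in Aspp1-/- against WT.

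The 5 comparisons, the size rule, the 26 gene lists, the rule for naming genes and 6 alternatives were chosen before the data were examined. The naming rule took the targeted genes, the 10 largest differences in each direction, up to 4 members past the rule of each list, all p53 targets, and the genes past the rule in both comparisons of the loss of the same gene. Other list members are given as examples of their list, and genes said to be ranked or chosen after their values were seen lie outside it. Each list's median log2 difference was placed among those of 10000 random lists of the same size drawn from 20 bins of mean expression, and a list below the 2.5th or above the 97.5th percentile was said to stand apart. Genes of a list that are expressed together move together, so these percentiles describe the arrays and are not p-values. Lists with fewer than 5 measured members, the targeted genes with their family and the sex check genes, were not placed. The lists covered p53 targets, stem cell, lymphoid-primed, T cell, B cell, granulocyte, monocyte, erythroid, megakaryocyte, mast cell, natural killer and stromal genes, G1/S, G2/M, quiescence, interferon, DNA damage, apoptosis, oxidative stress, immediate-early, Hippo, Notch, ribosomal protein and oxidative phosphorylation genes.

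The alternatives fixed in advance were quantile normalization, scaling to the median of probes well above background on all arrays, normexp background correction of the mean and background intensity (offset 50), the authors' value table, only probes well above background on all 4 arrays, and the mean of a gene's probes. A further 4 were added after seeing the data: leaving out transcripts within 10 Mb of the probes of Ppp1r13b or Trp53, lists without genes that another list also holds, ranking only genes well above background on all 4 arrays, and, in place of the size rule, the moderated t test of limma on an additive model of both genes, with p adjusted by the Benjamini-Hochberg method. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, quantile normalization and the additive model, were used.

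The steps were tested on simulated data. In 19117 genes simulated for Aspp1-/- against WT with noise of 0.162 on the log2 scale, the size rule found 5 of 67 genes changed 1.5-fold (7.46%), 37 of 67 changed 2-fold (55.2%) and 66 of 66 changed 4-fold, and no unchanged gene. All of these genes were simulated as well above background on every array and with the same noise. The result therefore says nothing of false calls among bounds, which were most of the genes past the rule. In lists simulated for p53-/- against WT, 7 of 200 unchanged lists (3.50%) and 44 of 50 lists shifted by 0.2 (88.0%) stood apart. The additive model found 183 of 191 simulated genes changed 4-fold, with 11 unchanged genes called, and 0 of 191 changed 2-fold. The 191 genes, out of 19117, were changed at once by the same fold, which eases the adjustment of p. In the data fewer genes may change and the targeted genes were not called, so this does not give the model's power there.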

Results

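Gene expression was measured in bone marrow cells sorted as lineage(-) Sca-1(+) cKit(+), or LSK cells, the fraction of mouse marrow that holds haematopoietic stem cells and multipotent progenitors. The cells came from male C57BL/6 mice of 4 genotypes: wild type (WT), Aspp1-/-, p53-/- and Aspp1-/-p53-/-. Aspp1, encoded by Ppp1r13b, is a protein that binds p53 and favours the transcription of its pro-apoptotic targets, and p53, encoded by Trp53, is a tumour suppressor that drives cell cycle arrest and apoptosis after stress. The p53 alleles were floxed and were deleted by Mx1-Cre, a recombinase under an interferon-responsive promoter that the double-stranded RNA analogue pIpC switches on. Mice of all 4 genotypes received 5 injections of pIpC at 8 weeks of age, and the cells were taken 4 weeks later, at 12 weeks. The series design gives a dose of 400 μg for all genotypes, whereas the sample labels read 400, 401, 402 and 403 μg for WT, Aspp1-/-, p53-/- and Aspp1-/-p53-/-. RNA of 3 mice was pooled for each genotype and hybridised to 1 array. There were no replicate arrays, so the differences given here come without a spread between replicates, and the only p-values are those of an additive model of both genes with 1 residual degree of freedom.

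Each array held 62976 spots, of which 59305 were gene spots. The share of probes well above background was 53.3% for WT, 52.9% for Aspp1-/-, 51.2% for p53-/- and 50.3% for Aspp1-/-p53-/-, and no spot was saturated. Across the 26465 probes well above background on all 4 arrays, the standard deviation of the log2 difference from WT was 0.240 for Aspp1-/-, 0.279 for p53-/- and 0.367 for Aspp1-/-p53-/-. The number of arrays limits the precision of every value.

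The targeted genes followed the genotypes. The Ppp1r13b probe (NM_011625, chromosome 12, 113066670 to 113066729, minus strand, mm9) gave a processed signal of 13182 in WT, 2247 in Aspp1-/-, 12759 in p53-/- and 2060 in Aspp1-/-p53-/- cells. Its log2 difference was −2.62 in Aspp1-/- against WT and −2.52 in Aspp1-/-p53-/- against p53-/-, with an error of 0.20 from the scanner's own error model for each. The Trp53 probe (NM_011640, chromosome 11, 69404204 to 69404263, plus strand, mm9) gave 730 in WT, 820 in Aspp1-/-, 164 in p53-/- and 169 in Aspp1-/-p53-/- cells. Its log2 difference was −2.18 in p53-/- against WT and −2.13 in Aspp1-/-p53-/- against Aspp1-/-, with an error of 0.15 for each. Both genes were still well above background on the arrays where they were targeted, and whether either probe lies in the deleted part of its gene is not given in the sources used here. The paralogues stayed under the 2-fold threshold: Ppp1r13l, which encodes the inhibitory member of the ASPP family, lay between −0.22 and 0.20 in the 5 comparisons, and Trp53bp2, which encodes ASPP2, between −0.08 and 0.09.

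**Figure D1:**
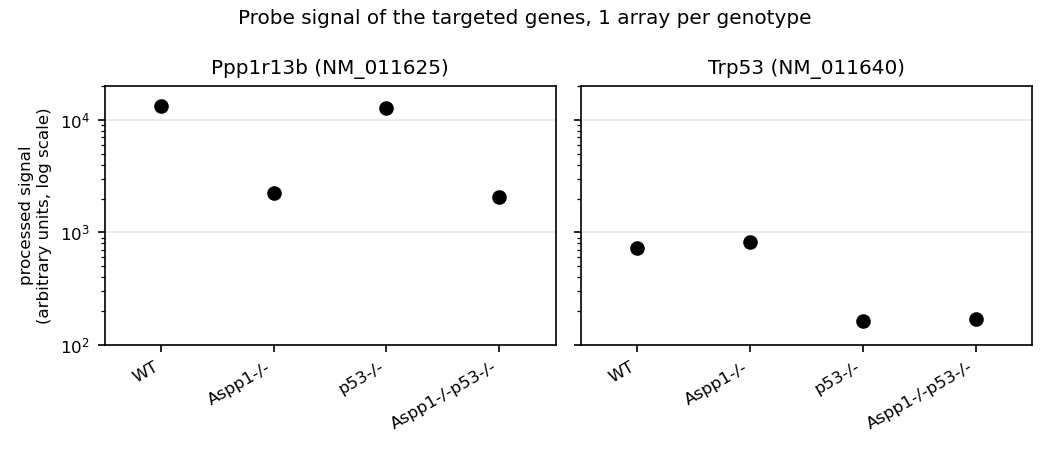
Processed probe signal (arbitrary units, log scale) of Ppp1r13b and Trp53 on the array of each genotype, 1 point per array. Ppp1r13b lies at 13182 and 12759 on the arrays with the intact gene and at 2247 and 2060 on the others, and Trp53 lies at 730 and 820 against 164 and 169.

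The comparison of Aspp1-/- with WT cells asked which genes differ when Aspp1 is lost and p53 is present. B-lineage genes were lower as a group: 11 of 14 measured members lay below 0, with a median log2 difference of −0.30, lower than that of all 10000 random lists of matched expression. Among them were Ebf1 at −0.63, the transcription factor that specifies the B lineage, Blnk at −0.58, an adaptor of B cell receptor signalling, and Igll1 at −0.53, a part of the surrogate light chain. Interferon response genes were lower in 28 of 37 members with a median of −0.12, among them Ifit3 at −0.48 and Irf7 at −0.48, and genes of monocytes, macrophages and dendritic cells were lower in 16 of 19 with a median of −0.15, among them Ly86 at −0.60 and Ccr2 at −0.50. G1/S and replication genes were higher in 20 of 22 members with a median of 0.13, among them Cdc6 at 0.25, a licensing factor of replication origins, and Mcm5 at 0.21, a part of the replicative helicase. Genes of DNA damage response and repair were higher in 23 of 30 members with a median of 0.10, and Gadd45b was at −0.70.

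Granulocyte and neutrophil genes were lower in 18 of 23 members in Aspp1-/- cells, with a median of −0.19, as were stromal and endothelial genes in 9 of 11 with a median of −0.27, natural killer cell genes in 7 of 9 with a median of −0.30, and mast cell and basophil genes in 6 of 8 with a median of −0.21. Quiescence and CDK inhibitor genes (median −0.09), erythroid genes (−0.09), lymphoid-primed progenitor genes (−0.08), ribosomal protein genes (−0.07), p53 target genes (−0.05) and immediate-early genes (−0.05) also stood on the low side of random lists, and of the immediate-early genes Egr3 fell at −2.54. None of the 34 measured p53 targets passed the 2-fold threshold: Cdkn1a was at −0.18, Mdm2 at −0.11, Bbc3 at −0.39 and Pmaip1 at −0.15. The medians of the other tested lists lay between −0.04 for megakaryocyte and platelet genes and 0.07 for oxidative phosphorylation genes, within the middle 95% of random lists.

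Among named genes well above background on all 4 arrays, a set ranked only after the values were seen, 5 rose and 7 fell at least 2-fold in Aspp1-/- cells. Those that rose were led by Nxpe2 at 2.60 and Adcy3, an adenylyl cyclase, at 2.18, and those that fell, after Ppp1r13b itself, by Lrmda at −2.20 and Kcna5, a voltage-gated potassium channel, at −1.45. In Aspp1-/-p53-/- against p53-/- cells Nxpe2, Adcy3, Lrmda and Kcna5 were at 0.03, 0.05, −0.33 and −0.02. Kcna5 was also at −1.27 in p53-/- and −1.28 in Aspp1-/-p53-/- cells against WT, so only the WT array differed. The largest differences by the rule fixed in advance were bounds, from probes well above background on 1 of the arrays: Chrng, an acetylcholine receptor subunit, at 4.11 or more, Emx2os at 4.07 or more, and Olfr715b, an olfactory receptor, at −4.99 or less. In all, 287 of 21682 genes or transcripts passed the threshold on the high side and 467 on the low side, 585 of them as bounds. With only probes well above background on all 4 arrays these counts were 53 and 47 (53% high against 38.1%), and with normexp background correction 118 and 100 (54.1% high). The p53 target, immediate-early, lymphoid-primed, stromal, ribosomal and mast cell lists lost their standing under at least 1 alternative.

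The comparison of p53-/- with WT cells asked which genes differ when p53 is lost and Aspp1 is present. p53 target genes were lower as a group: 31 of 34 measured members lay below 0, with a median of −0.22, lower than that of all 10000 random lists. Bbc3, which encodes the pro-apoptotic protein Puma, fell at least 2-fold at −1.13. Under that threshold were Phlda3, a repressor of Akt, at −0.87, Pmaip1, which encodes the pro-apoptotic protein Noxa, at −0.79, Cdkn1a, the inhibitor of cyclin-dependent kinases known as p21, at −0.73, Zmat3 at −0.69, and Mdm2, the ubiquitin ligase of p53, at −0.23. Interferon response genes were higher in 32 of 37 members with a median of 0.19, above that of all random lists. Ifit3 rose at 1.21, and Mx1 was at 0.64 and Mx2 at 0.59. These genes moved on arrays whose mice also carried Mx1-Cre.

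Immediate-early and handling stress genes, which cells switch on within minutes of a stimulus, were lower in 17 of 20 members in p53-/- cells, with a median of −0.38, below that of all random lists. Atf3, a stress-induced transcription factor, fell at −1.78 and Egr3 at −2.64 or less, while Klf6 was at −0.88, Klf2, a factor that keeps cells quiescent, at −0.87, and Fos at −0.30. Markers of other cell types stood apart in the same comparison: granulocyte genes had a median of −0.06, stromal genes of −0.16, B cell genes of 0.15, and monocyte, macrophage and dendritic cell genes of 0.10. Igll1 was at 0.42 and Vpreb1, another part of the surrogate light chain, at 0.33. Quiescence genes had a median of −0.10 and DNA damage genes of 0.08, and stem cell genes had a median of −0.03, a direction that turned to 0.02 when a gene's probes were averaged. The other tested lists lay within the middle 95%, between −0.08 for mast cell genes and 0.05 for lymphoid-primed genes.

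Among named genes well above background on all 4 arrays, ranked after the values were seen, 34 rose and 39 fell at least 2-fold in p53-/- cells. Those that fell included, besides Trp53, Lmna, which encodes the A-type nuclear lamins, at −1.80, Atf3 at −1.78, Trp53inp2 at −1.47, Atp1b2 at −1.43 and Mlf1, a myeloid leukaemia factor, at −1.41. Those that rose included Eml5 at 2.98, Rergl at 2.25 and Cd38, a surface NAD glycohydrolase, at 1.94. In Aspp1-/-p53-/- against WT cells these were at −0.16, −0.11 and −0.25, so their rise rests on the p53-/- array alone. By the rule fixed in advance the top gene was Sat2, a member of the spermine and spermidine acetyltransferase family, at 5.70 or more. This is 52.0-fold over the probe's own WT signal, which was not well above background, so it is not a strict lower limit. The Sat2 probe starts at 69437312 on chromosome 11 (mm9), 33.1 kb from the Trp53 probe. In all, 785 of 21851 genes or transcripts passed on the high side and 333 on the low side, 833 of them as bounds. Restricted to probes well above background on all 4 arrays, the counts were 105 and 104 (50.2% high against 70.2%), and with normexp 333 and 129. The p53-/- and WT arrays also differed in slide row and in Mx1-Cre, so these could not be told apart from the loss of p53, and the stromal, stem cell and DNA damage lists lost their standing under at least 1 alternative.

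The comparison of Aspp1-/-p53-/- with WT cells asked what the loss of both genes does. Immediate-early genes showed the largest shift of any tested list: 18 of 20 members lay below 0, 10 fell at least 2-fold, and the median was −1.01. Atf3 fell at −3.48, an 11.2-fold difference, Egr3, a zinc finger transcription factor, at −2.56 or less, Klf2 at −1.96 and Klf6 at −1.79. Of the heat-shock members of the same list, Hspa1a at 0.78 and Hspb1 at 0.58 lay above 0 and Dnajb1 at −0.48 below. p53 target genes were below 0 in 26 of 34 members, with a median of −0.22, and 6 of them fell at least 2-fold. These were Plk2, a polo-like kinase, at −2.06, Pmaip1 at −1.99, Cdkn1a at −1.54, Btg2, an antiproliferative gene, at −1.38, Bbc3 at −1.17 and Phlda3 at −1.10. A further Cdkn1a probe did not follow, at −0.13 here and between −0.17 and 0.04 in the other 4 comparisons, and another was well above background on the Aspp1-/- array only. Fas, which encodes a death receptor, was the only p53 target that rose at least 2-fold.

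Granulocyte and neutrophil genes were lower in 19 of 23 members in Aspp1-/-p53-/- cells, with a median of −0.53, and 9 fell at least 2-fold. Among these 9 were Retnlg at −2.35, Ltf (lactoferrin) at −1.92, Ngp at −1.84 and S100a8, a part of calprotectin, at −1.70. Members that did not pass included Mmp9 at −0.86 or less, Cebpe at −0.54, Fcnb at −0.53, Lyz2 at −0.36 and Ly6g at −0.05, and the primary granule genes Mpo, Elane and Ctsg at −0.05, −0.37 and 0.23. Quiescence genes had a median of −0.31, stromal genes of −0.35 with Cxcl12, the chemokine that retains stem cells in marrow, at −2.20, and natural killer cell genes of −0.30. Stem cell genes were below 0 in 26 of 35 members with a median of −0.10 and none past the threshold, as for Runx1 at −0.54 and Procr at −0.24 against Hoxa9 at 0.47. Megakaryocyte genes had a median of −0.08, with Plek at −1.08, and apoptosis genes of −0.07, a direction that turned to 0.07 when genes of other lists were left out. Interferon response genes were above 0 in 31 of 37 members with a median of 0.15, and DNA damage genes in 23 of 30 with a median of 0.12. The other tested lists lay within the middle 95%, between −0.11 for mast cell genes and 0.10 for G2/M genes.

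**Figure D2:**
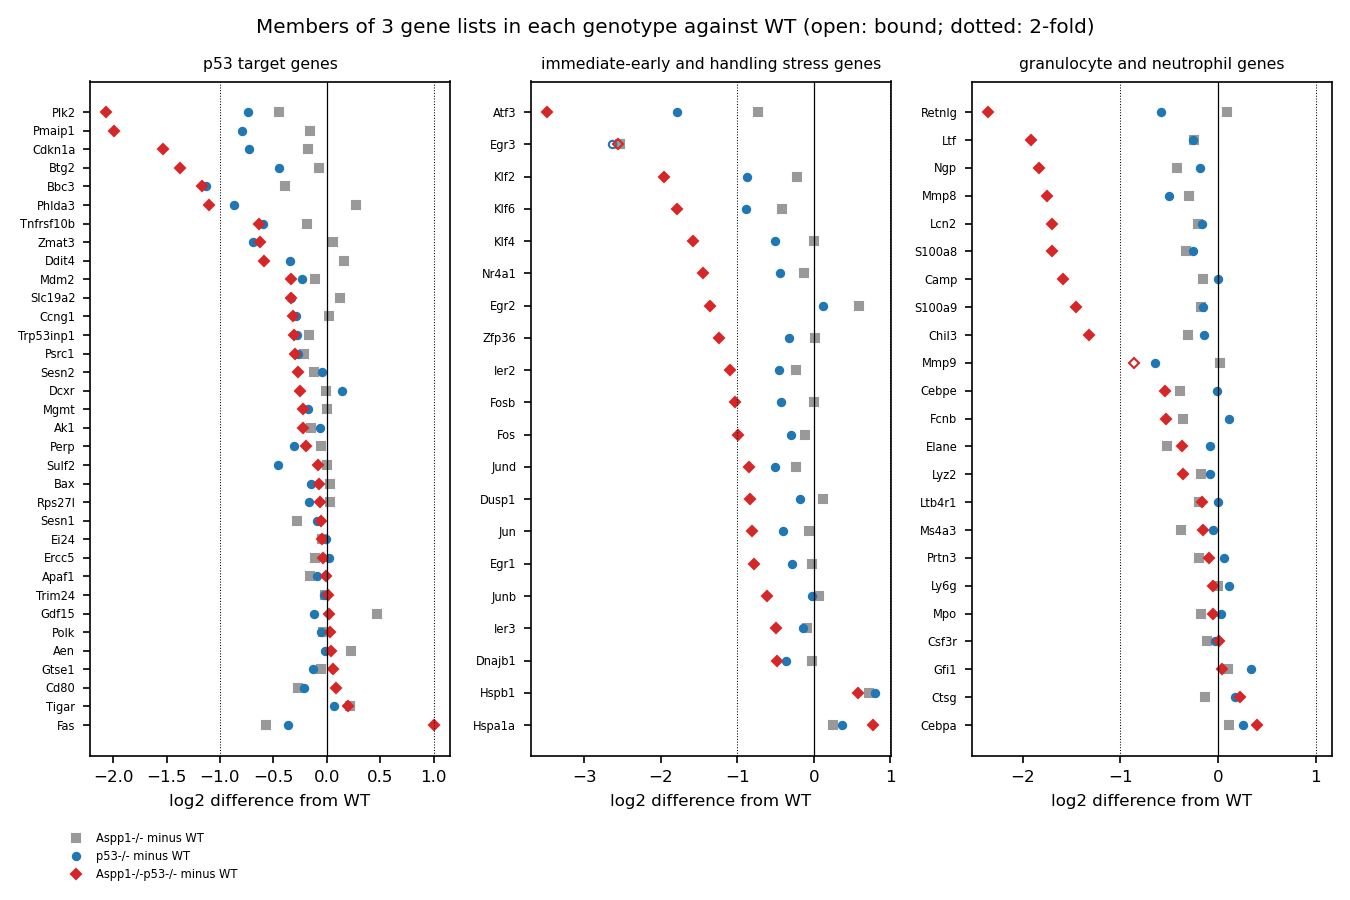
Log2 difference from WT of each member of 3 gene lists in Aspp1-/-, p53-/- and Aspp1-/-p53-/- cells, 1 array each, with open symbols for bounds and dotted lines at 2-fold. In Aspp1-/-p53-/- cells 6 p53 targets, 10 immediate-early genes and 9 granulocyte genes lay at or beyond 2-fold on the low side.

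Among named genes well above background on all 4 arrays, ranked after the values were seen, 44 rose and 158 fell at least 2-fold in Aspp1-/-p53-/- cells. By the rule fixed in advance, Fam71a at −4.53, Fosl2, a subunit of the AP-1 transcription factor, at −3.12 and Lmna at −3.10 were among the largest falls, and all were measured on both arrays. F3, which encodes tissue factor, was at −2.92, Cd83, an activation marker of lymphoid and dendritic cells, at −2.72, and Cd28, a T cell costimulatory receptor, at −2.49. Nrarp, a feedback inhibitor of Notch, fell at −1.65 and Vcam1 at −2.05. The largest rises were bounds, led by Sat2 at 5.60 or more and Rbfox3, a neuronal splicing factor, at 4.82 or more. In all, 766 of 21771 genes or transcripts passed on the high side and 528 on the low side, 808 of them as bounds. Probes well above background on all 4 arrays alone gave 164 and 276 (37.3% high against 59.2%), and with normexp 292 and 229. These arrays too differed in slide row and Mx1-Cre, and the natural killer and apoptosis lists lost their standing under at least 1 alternative.

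The comparison of Aspp1-/-p53-/- with p53-/- cells asked which genes differ with the loss of Aspp1 when p53 is already lost, on a pair of arrays that shared the slide row and Mx1-Cre. Immediate-early genes were below 0 in 18 of 19 members, with a median of −0.64 and 5 falls of at least 2-fold, among them Atf3 at −1.70, Egr2 at −1.47 and Klf2 at −1.08. Granulocyte genes were below 0 in 20 of 23 members, with a median of −0.30, and 9 fell at least 2-fold, among them Retnlg at −1.77, Ltf at −1.67 and Camp, the cathelicidin gene, at −1.58. B cell genes were below 0 in 12 of 13 members with a median of −0.23, quiescence genes in 14 of 18 with a median of −0.18, and stem cell genes in 26 of 35 with a median of −0.07. G2/M and mitosis genes were above 0 in 24 of 26 members with a median of 0.09, among them Hmmr at 0.17 and Aurkb, a mitotic kinase, at 0.14.

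p53 target genes did not stand apart between these arrays, with a median of −0.02 and 19 of 34 members below 0, but single members did pass: Plk2 fell at −1.32, Pmaip1 at −1.20, and Fas rose at 1.36. Cdkn1a was at −0.81, Btg2 at −0.93 and Bbc3 at −0.03. Stromal genes had a median of −0.16 and lymphoid-primed genes of −0.08, both on the low side. The other tested lists lay within the middle 95%, between −0.17 for natural killer cell genes and 0.06 for erythroid genes. Among named genes well above background on all 4 arrays, ranked after the values were seen, 29 rose and 84 fell at least 2-fold, with Mageb1 at 3.31, Gnaz at 2.58 and Mylk at 2.56 among the rises and Fam71a at −3.84, Eml5 at −3.14 and Cd38 at −2.19 among the falls. Eml5 and Cd38 were high on the p53-/- array only, and in Aspp1-/-p53-/- against WT cells they were at −0.16 and −0.25. By the rule fixed in advance the top genes were bounds, such as Rbfox3 at 4.37 or more and Il2ra, the interleukin-2 receptor alpha chain, at 4.17 or more. In all, 531 of 21292 genes or transcripts passed on the high side and 699 on the low side, 911 of them as bounds. With only probes well above background on all 4 arrays the counts were 102 and 172, and with normexp 252 and 299. The lymphoid-primed list lost its standing under normexp.

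The comparison of Aspp1-/-p53-/- with Aspp1-/- cells asked which genes differ with the loss of p53 when Aspp1 is already lost. p53 target genes were below 0 in 25 of 34 members, with a median of −0.15, lower than that of all random lists. Of these, 5 fell at least 2-fold: Pmaip1 at −1.84, Plk2 at −1.61, Phlda3 at −1.38, Cdkn1a at −1.36 and Btg2 at −1.30. Fas rose at 1.57. Immediate-early genes were below 0 in 19 of 20 members with a median of −0.86 and 8 falls of at least 2-fold, led by Atf3 at −2.76. Interferon response genes were above 0 in 33 of 37 members with a median of 0.23, with Ifit3 at 1.07 past the threshold and Mx1 at 0.97, Ifi27l2a at 0.92 and Irf7 at 0.82 under it.

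Several cell type lists also stood apart between these arrays. Monocyte, macrophage and dendritic cell genes were above 0 in 13 of 18 members with a median of 0.18, among them Ly86 at 0.85 and Irf8 at 0.58, B cell genes in 9 of 14 with a median of 0.22, among them Igll1 at 0.88, and erythroid genes in 11 of 17 with a median of 0.11. Granulocyte genes were below 0 in 15 of 23 members with a median of −0.17, including 9 falls of at least 2-fold such as Retnlg at −2.45. The other 14 granulocyte members had a median of 0.07 (8 above 0). Leaving out the members that fell most raises the median of any list, so this cannot show where the low standing came from. G2/M genes were above 0 in 23 of 26 members with a median of 0.11. Quiescence genes had a median of −0.29, stromal genes of −0.13 and stem cell genes of −0.06. Notch and lymphoid leukaemia genes had a median of −0.07, a direction that turned to 0.02 with normexp, and Nrarp fell at −1.35. The other tested lists lay within the middle 95%, between −0.07 for T cell genes and 0.07 for lymphoid-primed genes.

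Among named genes well above background on all 4 arrays, ranked after the values were seen, 45 rose at least 2-fold in Aspp1-/-p53-/- against Aspp1-/- cells and more fell. By the rule fixed in advance the top genes were Sat2 at 5.77 or more and Rbfox3 at 5.68 or more on the high side, and Fam71a at −4.55, measured on both arrays, on the low side. In all, 796 of 21607 genes or transcripts passed on the high side and 418 on the low side, 873 of them as bounds. Restricted to probes well above background on all 4 arrays, the counts were 121 and 184 (39.7% high against 65.6%), and with normexp 312 and 180. These arrays differed in slide row and Mx1-Cre as well, and the stem cell, stromal, erythroid and Notch lists lost their standing under at least 1 alternative.

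**Figure D3:**
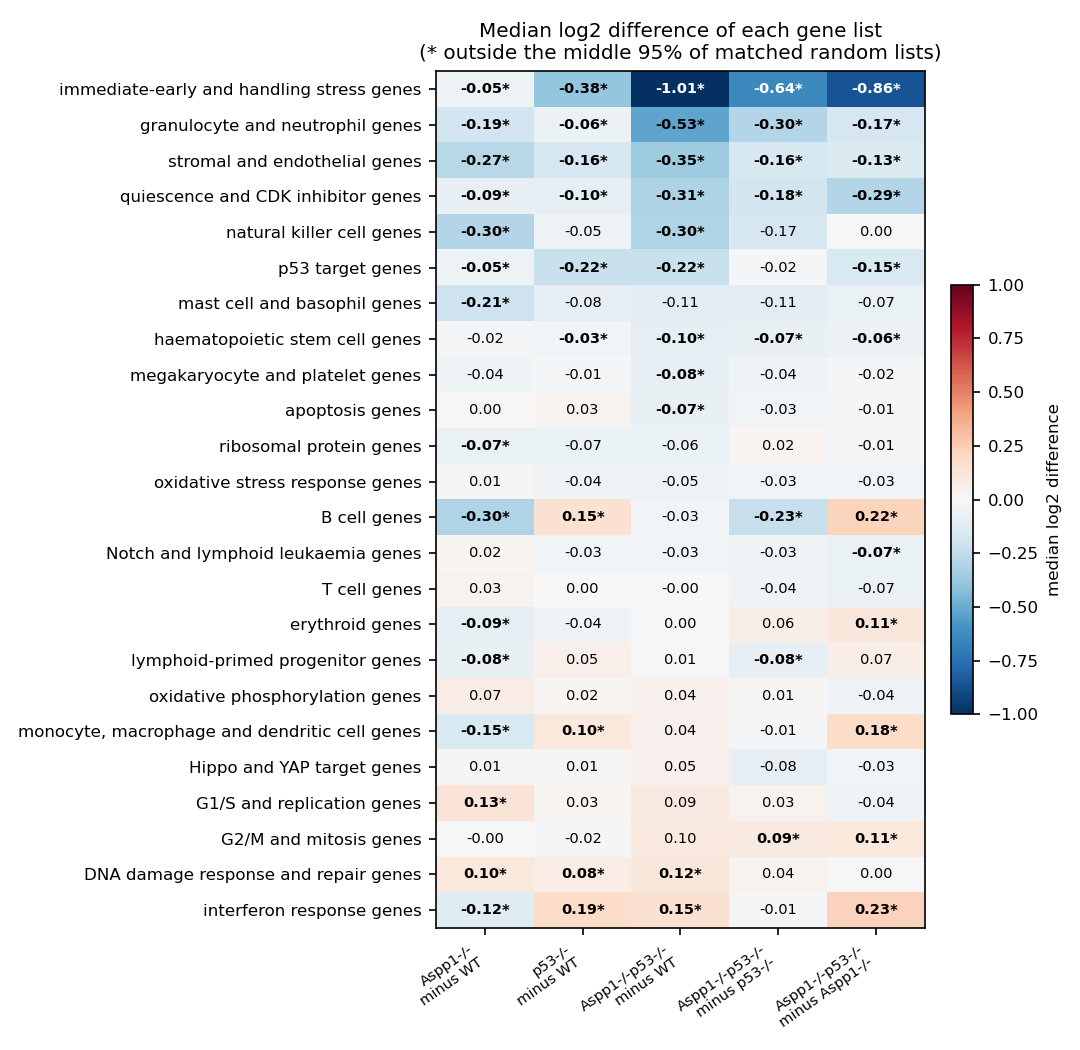
Median log2 difference of 24 gene lists in the 5 comparisons, with an asterisk where the median lay outside the middle 95% of 10000 random lists of matched expression. Immediate-early genes reach −1.01 in Aspp1-/-p53-/- against WT, p53 targets −0.22 in both genotypes without p53, and 3 asterisked medians changed sign under 1 alternative each (stem cell genes in p53-/- against WT, apoptosis genes in Aspp1-/-p53-/- against WT, Notch genes in Aspp1-/-p53-/- against Aspp1-/-).

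The loss of each gene was then compared in both backgrounds, using pairs of arrays with none in common. Both p53 comparisons set arrays of slide row 2, with Mx1-Cre, against arrays of row 1. Agreement between them therefore cannot be told apart from an effect of slide row or Mx1-Cre. Lmna (probe on chromosome 3, 88287262 to 88287321, mm9) fell with the loss of p53 in both backgrounds, at −1.80 and −2.30, as did Atf3 (chromosome 1, 192994547 to 192994606) at −1.78 and −2.76, Mlf1 at −1.41 and −1.62, Apold1, an endothelial early response gene, at −1.38 and −2.27, and Rgcc, a regulator of the cell cycle, at −1.37 and −2.30. A further Apold1 probe was at −0.44 and −1.30. Sat2 at 5.70 or more and 5.77 or more, Trim69, a ubiquitin ligase, at 1.85 and 1.99, C5ar2, a complement receptor, at 1.21 and 1.57, and Ifit3 at 1.21 and 1.07 rose in both. In total 76 genes or transcripts passed on the high side in both p53 comparisons, where independent lists would share 2.96, and 70 on the low side, against 2.78, while 13 passed in opposite directions, against 5.77. These 3 counts were 13, 23 and 2 with normexp and 11, 38 and 2 with only probes well above background on all 4 arrays. The counts by the reported values were over 20523 genes or transcripts measured in both comparisons. Across the 19117 well above background on all 4 arrays the correlation was r = 0.371 (Spearman's rho 0.338), and genes are not independent replicates.

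With the loss of Aspp1 no named RefSeq gene rose at least 2-fold in both backgrounds, and Ppp1r13b led those that fell in both. It was followed by bounds, Cypt15 at −2.14 or less and −3.82 or less and Agbl4, a carboxypeptidase, at −1.38 or less and −3.48 or less. Genes measured on all 4 arrays and low in both, chosen after their values were seen, were Eps8l1 at −1.19 and −0.89, Ear2, an eosinophil-associated ribonuclease, at −0.97 and −0.82, Lmna at −0.81 and −1.30, and Vcam1, an adhesion molecule, at −0.78 and −1.37. In total 27 genes or transcripts passed on the high side in both Aspp1 comparisons, against 0.733 for independent lists, 18 on the low side, against 1.5, and 13 in opposite directions, against 2.12. These counts were 15, 2 and 1 with normexp and 22, 6 and 1 with only probes well above background on all 4 arrays. Of the 27, 12 remained when transcripts within 10 Mb of the targeted genes were left out, an alternative chosen after seeing the data. In the immunoglobulin heavy-chain stretch of chromosome 12, within 10 Mb of the Ppp1r13b probe, 15 transcripts passed on the high side in both. The counts by the reported values were over 20039 genes or transcripts measured in both comparisons. Across the 19117 well above background on all 4 arrays the correlation was r = 0.233 (rho 0.252).

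**Figure D4:**
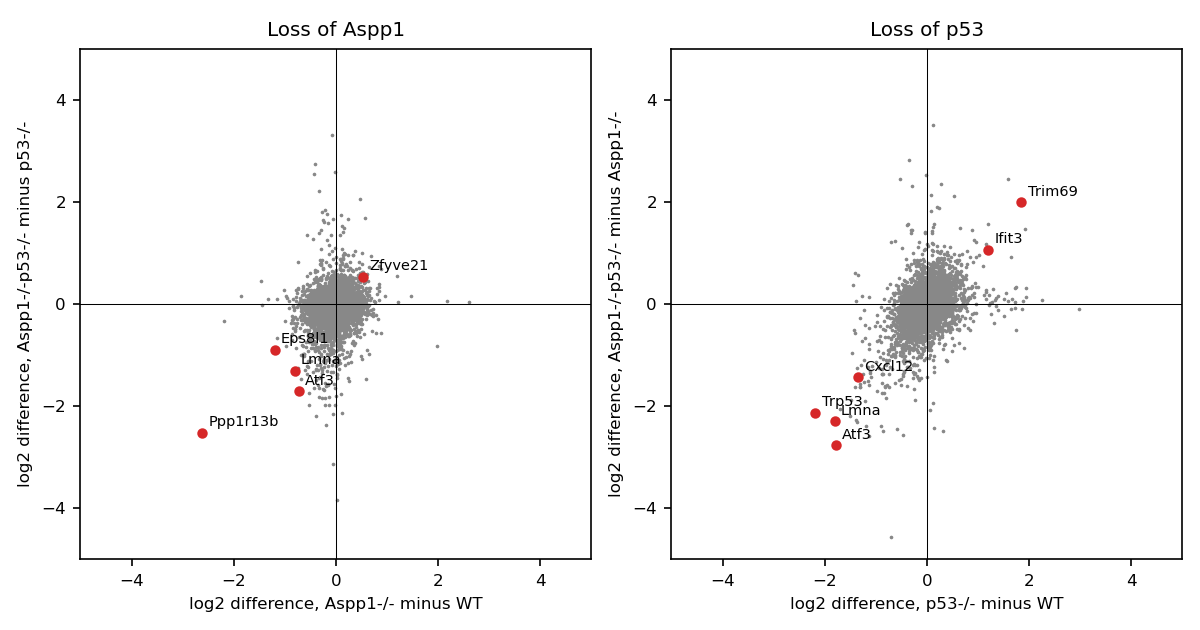
Log2 differences of RefSeq genes well above background on all 4 arrays, 1 grey point per gene, with the loss of Aspp1 (left) or p53 (right) in cells with the other gene intact (horizontal axis) and lost (vertical axis). Ppp1r13b lies at −2.62 and −2.52 and Trp53 at −2.18 and −2.13, and Lmna and Atf3 lie below 0 on both axes of each plot.

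Across genes, the standard deviation was 0.205 for the Aspp1 contrast, 0.238 for the p53 contrast and 0.162 for their interaction, 3 combinations of the arrays that would share the same expected value with no effects. With the loss of Aspp1, immediate-early and granulocyte genes, chosen here after their values were seen, had unlike differences in the 2 backgrounds: Atf3 was at −0.72 with p53 present and −1.70 with p53 lost, Klf2 at −0.22 and −1.08, Ltf at −0.25 and −1.67, and Retnlg at 0.10 and −1.77. Among genes well above background on all 4 arrays, the change with the loss of Aspp1 was at least 2-fold higher without p53 than with it for 147 and at least 2-fold lower for 201, and these counts were 70 and 74 with normexp and 256 and 345 when a gene's probes were averaged. With 1 array per genotype no residual degree of freedom was left to test this departure.

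An additive model of both genes over the 4 arrays, added after seeing the data, takes the interaction as noise, and its p53 term also carries slide row and Mx1-Cre. Except under normexp it did not call even the targeted genes, so a gene it did not call cannot be taken as unchanged. Among 19117 genes or transcripts, limma called none for either gene at an adjusted p under 0.05, with 1646 for Aspp1 and 2347 for p53 at an unadjusted p under 0.05. The targeted genes Ppp1r13b and Trp53 ranked first in their terms, with adjusted p of 0.527 and 0.310. With normexp the model called none on the high side and 1 on the low side for Aspp1, and 3 and 31 for p53.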

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

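The tests of slide row or Mx1-Cre, of granulocyte-committed cells, of handling stress in the step from WT to p53-/- and of neutrophils in the step from p53-/- to Aspp1-/-p53-/- were chosen after the results they weigh were seen, and the others before their own values were seen.

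Some genes passed the 2-fold threshold in opposite directions when the same gene was lost in the 2 backgrounds, and the difference was not tested. With the loss of Aspp1, in cells with p53 and in cells without it, Ankrd34a was at −1.64 or less and 2.04 or more, Syce1, a component of the synaptonemal complex, at 2.43 or more and −1.44 or less, Ifnk, an interferon, at −1.35 and 1.93 or more, and Aknad1 at −1.34 or less and 2.24 or more. With the loss of p53, in cells with Aspp1 and in cells without it, Syce1 was at 1.96 or more and −1.91 or less, Ifnk at −1.40 or less and 1.88, and Bglap2, an osteocalcin gene, at −1.01 or less and 1.62. Most of these values are bounds from probes that were not well above background on every array, and no list stood apart in opposite directions in a pair of this kind by the reported values. Under alternatives some did with the loss of Aspp1: erythroid genes, low in cells with p53, stood apart high in cells without it under quantile normalization (0.087), normexp (0.089) and the mean of a gene's probes (0.080), and under normexp G2/M genes stood apart low in cells with p53 (−0.038) and high in cells without it.

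Immediate-early genes were lower from WT to Aspp1-/- to p53-/- to Aspp1-/-p53-/-, with medians against WT of −0.05, −0.38 and −1.01. Slide row or Mx1-Cre as the whole cause is argued against by the p53-/- and Aspp1-/-p53-/- arrays, which share both and still differed, at percentile 0 of random lists, although the step from WT to p53-/- cannot be told apart from them and the slide column stays open. Handling stress that also raises heat-shock genes would need a median of −0.505 or less for 6 further heat-shock genes in Aspp1-/-p53-/- against WT. Their median was −0.0212 (−0.27 to 0.11, a range from resampling the genes). Such ranges, here and below, show spread between genes and not between pools or arrays. The bound written beforehand, a median over 0, was not met, and the comparison with the spread was added once the value was known. The step from WT to p53-/- stays open, since all 6 were lower there with a median of −0.115 (−0.34 to −0.03) beside a bound of −0.192. Fewer neutrophils carrying these transcripts would need the other neutrophil genes to fall as far in p53-/- against WT, and their median there was −0.135 (−0.23 to −0.03) against a bound of −0.284, but for the step from p53-/- to Aspp1-/-p53-/- it was −0.635 (−0.99 to −0.26) beside −0.64 for the immediate-early genes, which leaves fewer neutrophils open there. Handling that leaves heat-shock genes alone and an effect of the genotypes on this programme remain open, and the latter may be considered only as a hypothesis, since the pattern was found on the same 4 arrays.

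A part of the granulocyte list, 9 genes such as Ltf, Camp and S100a8, was lower in Aspp1-/-p53-/- than in the other 3 genotypes, with medians of −1.70 against WT, −1.54 against p53-/- and −1.43 against Aspp1-/-; these are the members that fell at least 2-fold against WT, so the medians and the bounds taken from them reflect that choice, and granule genes such as Mpo and Ctsg did not follow. For slide row or Mx1-Cre, the 9 genes had a median of −0.185 in p53-/- against WT, where −0.850 was the bound. This cannot decide, since the 9 were chosen as low on the Aspp1-/-p53-/- array. The whole list, fixed in advance, was at −0.30 in Aspp1-/-p53-/- against p53-/- (20 of 23 below 0). These arrays share both, which argues against slide row or Mx1-Cre as the whole cause of the list's fall. A lower share of all granulocyte-committed cells stays open. In Aspp1-/-p53-/- against p53-/- 8 early genes such as Mpo had a median of only −0.0887 (−0.29 to 0.05, bound −0.308). Yet this stood apart at percentile 0.52, and the list without the 9 was at −0.16 (11 of 14 below 0). Against Aspp1-/- the early genes stood apart high, at 0.14 (7 of 8 above 0, percentile 99.96), and the list without the 9 was at 0.07 (8 of 14 above 0). Against WT the early genes were at −0.02 and the list without the 9 at −0.13 (10 of 14 below 0). The early genes' medians against Aspp1-/- and WT go against a lower share, but genes that uncommitted cells also express could hide a small one. Fewer mature neutrophils in the sorted cells, which the lineage(-) gate is meant to remove, could neither be excluded nor supported, since the other neutrophil genes, among them Lrg1 at −1.01 and Wfdc21 at −1.22, had a median of −0.635 (14 of 15 below 0) in the same comparison, between the bounds of −0.770 and −0.308. A carry-over of neutrophils that differs between pools and a change of these transcripts within LSK cells also remain candidate explanations. The slide column, which was 4 for the Aspp1-/-p53-/- array only, stays open as well.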

How the results depend on the processing

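The alternatives that left out transcripts near the targeted genes or genes shared between lists, the ranking of genes well above background on all 4 arrays, and the additive model, were chosen after seeing the data; the other 6 were planned. No paired analysis was possible because each genotype has 1 array, so the groups compared share only 1 replicate number. The additive model called genes only under normexp, 1 for Aspp1 and 3 high and 31 low for p53. No setting moved the median of all genes by as much as 0.1. Of the counts, correlations and standard deviations recomputed, 139 stayed within 1.5 times of the reported value and 36 did not. Of the list medians 739 kept their side of the limits, 24 no longer stood apart and 24 newly did. A further 3 that stood apart changed sign and no longer did. The sign was compared only for medians that stood apart by the reported values. Of the values of named genes 2155 stayed past the threshold or under it as before and 61 fell short of it, 53 of them under normexp. None past the threshold changed sign, and sign changes among values under it were not counted. The scaling to the median of probes well above background on all arrays moved no count or list across its limit. Signal over background limits these results: most genes past the threshold were dim on 1 array. Except where stated, the cause was not tested.

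Normexp, which adds an offset that shrinks the differences of dim probes, gave these counts past the threshold, high and low: 118 and 100 in Aspp1-/- against WT, 333 and 129 in p53-/- against WT, 292 and 229 in Aspp1-/-p53-/- against WT, 252 and 299 against p53-/-, and 312 and 180 against Aspp1-/-. With the loss of Aspp1 15 were high in both backgrounds, 2 low and 1 opposite, with the loss of p53 13, 23 and 2, and departures from additivity numbered 70 above and 74 below.

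With only probes well above background on all 4 arrays, which removes the bounds, the counts were 53 and 47, 105 and 104, 164 and 276, 102 and 172, and 121 and 184 in the same order. With the loss of Aspp1 6 were low in both and 1 opposite, and with the loss of p53 11 were high, 38 low and 2 opposite. The mean of a gene's probes gave 256 departures from additivity above and 345 below. Without transcripts near the targeted genes 12 transcripts were high in both Aspp1 comparisons. The immunoglobulin heavy-chain stretch near Ppp1r13b, which this leaves out, held 15 that were high in both.

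Under normexp the Notch median in Aspp1-/-p53-/- against Aspp1-/- changed sign to 0.023. Newly apart were erythroid genes in Aspp1-/-p53-/- against p53-/- (0.089), G2/M genes in Aspp1-/- against WT (−0.038), megakaryocyte (−0.062), mast cell (−0.12) and oxidative stress genes (−0.057) in p53-/- against WT, mast cell (−0.13), oxidative stress (−0.078) and ribosomal genes (−0.094) in Aspp1-/-p53-/- against WT, and oxidative stress genes against Aspp1-/- (−0.078). No longer apart were stem cell (−0.028) and DNA damage genes (0.046) in p53-/- against WT, natural killer genes in Aspp1-/-p53-/- against WT (−0.055), lymphoid-primed genes against p53-/- (−0.040), and stem cell (−0.043) and stromal genes (−0.074) against Aspp1-/-.

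With the mean of a gene's probes the stem cell median in p53-/- against WT changed sign to 0.018. Newly apart were megakaryocyte genes in p53-/- against WT (−0.070), oxidative phosphorylation genes in Aspp1-/- against WT (0.088), and erythroid (0.080) and DNA damage genes (0.050) in Aspp1-/-p53-/- against p53-/-. No longer apart were p53 targets (−0.024), lymphoid-primed (−0.055) and stromal genes (−0.14) in Aspp1-/- against WT, stromal (−0.082) and DNA damage genes (0.057) in p53-/- against WT, and Notch genes in Aspp1-/-p53-/- against Aspp1-/- (−0.025).

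Under quantile normalization newly apart were erythroid (−0.10) and oxidative stress genes (−0.054) in p53-/- against WT, G1/S genes in Aspp1-/-p53-/- against WT (0.12), erythroid genes against p53-/- (0.087) and lymphoid-primed genes against Aspp1-/- (0.12). No longer apart were immediate-early (−0.012) and ribosomal genes (0.00) in Aspp1-/- against WT, DNA damage genes in p53-/- against WT (0.051), and erythroid (0.087), stromal (−0.14) and Notch genes (−0.033) in Aspp1-/-p53-/- against Aspp1-/-.

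With only probes well above background on all 4 arrays newly apart were oxidative phosphorylation genes in Aspp1-/- against WT (0.075), natural killer genes in p53-/- against WT (−0.17), G1/S genes in Aspp1-/-p53-/- against WT (0.098) and mast cell genes against p53-/- (−0.15), and immediate-early genes in Aspp1-/- against WT (−0.030) no longer were. In the authors' value table DNA damage genes in p53-/- against WT (0.071) no longer stood apart.

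Without genes shared between lists the apoptosis median in Aspp1-/-p53-/- against WT changed sign to 0.065, since low members such as Pmaip1 and Bbc3 are also p53 targets. Newly apart were apoptosis (0.12) and megakaryocyte genes (−0.048) in p53-/- against WT, and no longer apart were mast cell genes in Aspp1-/- against WT (−0.13), natural killer genes in Aspp1-/-p53-/- against WT (−0.17), and stem cell (−0.046) and Notch genes (−0.038) against Aspp1-/-.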

Other observations

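The test of B-lineage cells was chosen after its result was seen, and the tests of linked DNA before.

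Further genes outside the lists, chosen after their values were seen, differed between Aspp1-/-p53-/- and p53-/- cells: Cd83 fell at −1.82 and Fosl2 at −1.98, and Vcan, which encodes the matrix proteoglycan versican, rose at 1.60. Fam71a, whose probe starts at 192986463 on chromosome 1 (mm9), and Atf3, whose probe starts at 192994547, both fell in Aspp1-/-p53-/- against WT cells, at −4.53 and −3.48. The mast cell tryptase gene Tpsab1 was at 4.14 or more in p53-/- against WT and 4.93 or more in Aspp1-/-p53-/- against Aspp1-/- cells, whereas its list did not stand apart in either comparison. Xcl1, a chemokine of natural killer and T cells, rose at 2.69 in p53-/- against WT cells while its list had a median of −0.05.

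Bcl2l11, which encodes the pro-apoptotic protein Bim, was at −0.47 in Aspp1-/- and −0.71 in p53-/- cells and fell at −1.30 in Aspp1-/-p53-/- cells, all against WT, while its further probe was at 0.07, −0.18 and −0.40. Mycn was at 0.47, 0.71 and 0.96 and Hes1, a Notch target, at −0.45, −0.45 and −0.68 in the same order. Of the sex check genes, the Y-linked Ddx3y, Eif2s3y and Uty were well above background on all 4 arrays, with differences from WT between −0.36 and 0.41, and Xist was well above background only on the Aspp1-/- array, at a bound of 0.78 or more against WT. T cell genes had medians of 0.03 in Aspp1-/- and 0.00 in p53-/- against WT. Oxidative stress genes had medians of 0.01, −0.04 and −0.05 and Hippo and YAP target genes of 0.01, 0.01 and 0.05 in Aspp1-/-, p53-/- and Aspp1-/-p53-/- against WT.

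Transcripts near a targeted gene were compared between both contrasts of its loss, and 71.7% had the same sign near Ppp1r13b and 66.2% near Trp53. Within 10 Mb of the Ppp1r13b probe the Aspp1 comparisons correlated at r = 0.772 across 219 transcripts well above background on all 4 arrays, above 100% of 483 windows elsewhere (median 0.177, highest 0.735), and at 0.512 across 164 without the immunoglobulin heavy-chain stretch (chromosome 12, 114392029 to 117298954, mm9). The value of 0.512 lies below the highest window and was not ranked among the windows. Linked donor-strain DNA around Ppp1r13b would give a high correlation, as found with the stretch included (0.772). It may account for neighbours such as Zfyve21 at 0.53 and 0.54 and Tedc1 at −0.85 and −0.70. This is a hypothesis, since the labels give a C57BL/6 background and not the strain of the targeted cells. Around Trp53 the correlation was 0.418 across 337 transcripts, above only 63.1% of windows and beside 0.369 for transcripts elsewhere. No regional pattern beyond that of other windows was seen, but this cannot decide on linked DNA there. Both p53 comparisons share slide row and Mx1-Cre, which may raise the correlation in every window, and bounds such as Sat2 were left out of it. Single neighbours such as Sat2 and Atp1b2 stay open. Fewer B-lineage cells would lower the heavy-chain stretch. Of its transcripts, here with bounds included, that moved the same way in both comparisons 40 were higher and 23 lower (63.5% higher). The stretch lies within the window where linked DNA stays open, so this cannot decide whether B-lineage cells were fewer. The B cell list was low in both comparisons, with medians of −0.30 (11 of 14 below 0) and −0.23 (12 of 13 below 0).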
